A study of Bacillus subtilis subsp. subtilis str. 168 with 7 samples.

How the data were processed

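RNA from *Bacillus subtilis* cells grown with and without 0.1 mM added manganese was measured on 7 two-colour spotted arrays, 3 for the agar experiment (3 days at 30 °C on 1.5% agar) and 4 for the liquid experiment (overnight, 225 rpm). Both conditions of a replicate were hybridised to one array. The dye of each condition and the grouping of arrays were taken from the labels, which state biological replicates and dye swaps.

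The scanner files hold signal and local background intensities of each spot in both channels, which per the file headers were not normalized, with the spots that the authors excluded set to 0. They also hold intensities from which the authors had subtracted background in 2 steps, not used here. The deposited processed values are, from a comparison with the scanner values, natural log ratios per array of without over with manganese, and the authors' tool and normalization for them are not given. Their slopes against the log2 ratio of with over without manganese were -0.64 to -0.68. They served as an alternative.

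Spots excluded by the authors were left out (285 to 389 per array). Signals were background-corrected by normexp with an offset of 50. Log2 ratios of Cy5 over Cy3 were normalized within each array by loess (span 0.3, 4 iterations) with weight 0 for control spots, and the 2 spots of a gene were averaged. Print blocks were tested by the rank correlation (rho) of spot brightness with the other arrays of the experiment. On agar replicate 3, 12 blocks had a rho of -0.456 to 0.377, and on liquid replicate 4, 7 blocks had one of -0.191 to 0.365. These lay under a limit of 0.5, the remaining blocks of the affected arrays were at 0.891 and 0.869 or more, and these 19 blocks were left out. A further block of agar replicate 3 had no rho, since 0 of its 56 spots were over their background, and was left out too. This step was decided after the data were examined and uses brightness, not the ratio. Genes were named by locus tag from a reference table of assembly ASM904v1 (4038 genes) or from the file (68 genes). The genome build behind the probes is not stated, and no coordinates are given.

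Genes with values on at least 2 arrays of each experiment (3999) were fitted with limma 3.58.1 in R 4.3.3. The fit had one coefficient for manganese on agar, one for manganese in liquid and a common dye intercept, with moderated variances (5.56 prior degrees of freedom). The difference between the experiments was agar minus liquid. P-values were adjusted by Benjamini-Hochberg over the 3999 genes and called under 0.05. The median SE of a log2 ratio was 0.154 on agar, 0.128 in liquid and 0.200 for the difference. For the dye intercept, limma called 0 genes after adjustment, 589 had an unadjusted p under 0.05, and its median size was 0.111.

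A gene counted as above background in a condition on an array when the mean signal of its spots exceeded 2 times their mean background. Where a condition stayed below on every array of an experiment, a bound was computed from channel levels after loess and quantile normalization of average intensity. The level of that condition was raised on each array to the lowest level of any gene above background there, unless it was already higher. This floor is not the gene's own background limit, so the bounds are approximate and not strict lower limits. Where both conditions stayed below, no fold is given. Effects on agar and in liquid were correlated across genes from the mean ratio of each experiment's own arrays.

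The 34 gene lists were fixed before the data were examined, as were the comparisons, the tests and most alternatives. Members slrA, skfC, pykA and mqo were not matched by the names used, which does not show that the array holds no probe for them. Lists were tested with camera (preset correlation 0.01, and with an estimated one) and fry on the 3212 genes with values on all 7 arrays, for the 33 lists of at least 5 such genes, with Benjamini-Hochberg adjustment over the lists. Named genes are all tested members of the manganese homeostasis list, the 10 largest fitted increases and decreases among genes called and moving one way on every array, and up to 4 called members of smallest p from each list, or 2 members of a list with none. The 5 largest fitted differences between experiments in each direction are named as well, a choice made after the data were examined.

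Alternatives covered background correction, normalization, scaling between arrays, excluded spots, the dye term, separate fits, array weights, variance trend, a background filter (above background in at least 1 channel on every array of the comparison with a value), the deposited values, thresholds and each array left out. Those added after the data were examined were the left-out blocks kept or moved by 1 column and the liquid labels exchanged. The limma fit was tested on simulated log2 ratios of 3999 genes with normal noise, with 66 or 67 genes changed per experiment at each fold size. Background correction, loess, spot averaging and the limit set by background were not simulated. The rates therefore do not carry over to genes near background or to data in which most genes change. At a 2-fold change, 95.5% of changed genes were recovered on agar and 100.0% in liquid, at 1.5-fold 64.2% and 85.1%, and of the calls 5.98% and 7.77% were false. For simulated differences, 75.4% of 391 were recovered with 6.35% of calls false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.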

Results

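Transcript levels of wild-type *Bacillus subtilis*, a spore-forming soil bacterium, were compared between cells grown with 0.1 mM added manganese and cells grown without it, in the sporulation medium 2xSG. The question addressed was which transcripts follow the manganese supply, in colonies on solid medium and in liquid culture. In the agar experiment, cells were spotted on plates and harvested after 3 days at 30 °C. In the liquid experiment, cells were grown overnight with shaking at 225 rpm. Per the labels, RNA came from separate biological replicate cultures. Each of the 7 two-colour arrays carried RNA of both conditions, one in Cy3 and the other in Cy5, with 3 arrays for agar and 4 for liquid. The RNA labelled as with manganese was in Cy5 on 2 agar arrays and 1 agar array had it in Cy3, while the liquid arrays held each orientation on 2 arrays. Of the 4106 genes on the array, 3999 had a value on at least 2 arrays of each experiment and were tested.

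Signal differed between the experiments. On the agar arrays, 43.1% to 96.0% of the gene spots per channel lay above 2 times their local background, against 17.0% to 45.3% on the liquid arrays. In liquid, 1045 of the 3999 genes were above that level in each condition on at least 1 array, and 1905 were below it in both on all arrays, against 3610 and 106 on agar. The oriented log2 ratios of all genes correlated within an experiment with Pearson's r of 0.90 to 0.95 on agar and 0.91 to 0.96 in liquid. Between an agar and a liquid array, r was -0.38 to -0.25. These correlations are across genes, which are not independent replicates. On agar replicate 3, 12 of 36 print blocks did not line up with the other arrays and 1 more had no spot over its background (1136 gene spots in all 13). On liquid replicate 4, 7 of 36 (312 gene spots) did not line up. These blocks were left out, so some genes rest on fewer arrays. The number of arrays limits the precision of every value below.

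Values are log2 ratios of with over without manganese ± SE from the limma fit (n = 3 agar arrays or 4 liquid arrays unless fewer are stated), and every adjusted p for a gene is limma's with Benjamini-Hochberg adjustment over the 3999 genes. A gene whose signal in a condition was below 2 times background on every array has only an approximate bound, given as at least N-fold. It rests on the lowest level of any gene above background, not on the gene's own background, and is not a strict lower limit. Such bounds are set per channel, and on agar, where the dye orientations are unequal in number, they are open to dye bias.

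On agar, the genes of both manganese importers fell with added manganese. The proton-coupled transporter gene mntH (BSU04360) had a log2 ratio of -3.45 ± 0.25 and mntA (BSU30770), the first gene of the mntABCD ABC transporter operon, one of -3.48 ± 0.28. The other operon genes were mntB (-2.58 ± 0.28), mntC (-2.63 ± 0.28) and mntD (-0.76 ± 0.12), each lower on 3 of 3 arrays with an adjusted p of at most 2.53e-04. MntR, the manganese-responsive repressor of these genes, is also known to activate the exporter genes mneP and mneS. The log2 ratio of mneS was 0.45 ± 0.14 (limma adjusted p = 0.0163), and it no longer passed when any single agar array was left out (adjusted p = 0.0503 to 0.0894). The mneP gene was also called higher (limma adjusted p = 0.0151) but lay below background in both conditions, and was not called without agar replicate 1 (limma adjusted p = 0.179) or 3 (limma adjusted p = 0.092). Without agar replicate 1 the ratios of mntH and mntA were -2.76 and -4.11. Among genes with a manganese-sensing riboswitch, yybP (0.81 ± 0.17, 2 arrays) rose, although without agar replicate 1 its ratio was 0.65 and rested on a single agar array. The ratio of ykoY (0.18 ± 0.14, limma adjusted p = 0.304) did not pass the test. Nor did that of mntR itself (0.27 ± 0.21, 2 arrays, limma adjusted p = 0.298). The ratio of mntR was 0.78 without replicate 1 and -0.25 without replicate 2, each resting on a single agar array. Over the manganese homeostasis list of 10 genes, 3 rose and 5 fell, and the list did not shift in one direction against the other genes. Because it joins genes that MntR represses with genes that it activates, a test of a common direction cannot show whether the list responded. For the manganese homeostasis list, camera gave an adjusted p of 0.134, and an adjusted p of 0.401 with an estimated correlation. Without agar replicate 1 its camera adjusted p was 0.0481.

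Of the 10 largest increases, 5 were genes of the late mother cell list. The 10 were cgeB (6.0 ± 0.14), yhfD (5.86 ± 0.22), yurS (5.80 ± 0.14, 2 arrays), gerE (5.49 ± 0.19), sspG (5.49 ± 0.13), cgeC (5.43 ± 0.21), yybO (5.42 ± 0.17, 2 arrays), spmH (5.39 ± 0.22), yjcB (5.25 ± 0.17) and cgeA (5.21 ± 0.23, 2 arrays), all with an adjusted p of at most 2.34e-07. Without agar replicate 1 the value of cgeA was 4.55, and without replicate 2 it was 5.87. GerE is the last transcription factor of the mother cell line, and the cge genes act in the maturation of the spore's outermost layer. In the late mother cell and spore coat list (SigK dependent), 51 of 52 genes rose and 1 fell, with a median of 3.97, among them cotM (4.88 ± 0.16) and cotW (4.95 ± 0.16). The late mother cell list had a camera adjusted p of 7.38e-16, and an adjusted p of 0.321 with an estimated correlation. Forespore genes (SigF and SigG dependent) rose in 42 of 50 cases and fell in 1, with a median of 1.76. For the forespore list, camera gave an adjusted p of 1.25e-09, and an adjusted p of 0.122 with an estimated correlation. Those of smallest p were the small acid-soluble spore protein genes sspP (4.28 ± 0.13), sspN (4.02 ± 0.13), sspO (4.12 ± 0.15) and sspD (3.86 ± 0.13). Of 43 early mother cell genes (SigE dependent), 39 rose and 0 fell (median 1.42), for example mmgD (3.28 ± 0.16) and spoVM (2.53 ± 0.14). The early mother cell list had a camera adjusted p of 2.01e-09, and an adjusted p of 0.387 with an estimated correlation. The early sporulation list moved the other way in its called members, with 1 higher and 7 lower of 14, including spoIIE (-1.57 ± 0.20) and spo0A (-0.56 ± 0.13), and with each array left out in turn 0 higher and 2 to 6 lower. The list as a whole did not pass. For the early sporulation list, camera gave an adjusted p of 0.161, and an adjusted p of 0.613 with an estimated correlation. Its median turned from -0.38 to 0.04 when the arrays were scaled to one spread.

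Biofilm matrix genes rose in 17 of 19 cases, with 0 lower and a median of 2.08. The biofilm matrix list had a camera adjusted p of 7.82e-05, and an adjusted p of 0.464 with an estimated correlation. The exopolysaccharide genes epsA (3.31 ± 0.18) and epsB (3.44 ± 0.20, 2 arrays), the amyloid fibre anchoring gene tapA (3.45 ± 0.22, 2 arrays) and the hydrophobin gene bslA (1.76 ± 0.14) were those of smallest p. Of the 23 biofilm and sporulation regulators, 6 rose and 10 fell. The antirepressor gene sinI (1.48 ± 0.18) and the regulator gene slrR (1.25 ± 0.15) were among the former, and kinD (-1.69 ± 0.17) and degQ (-1.50 ± 0.13) among the latter. For the biofilm and sporulation regulator list, camera gave an adjusted p of 0.329, and an adjusted p of 0.613 with an estimated correlation. All 11 tested genes of the cannibalism toxin list rose (median 2.08), with skfB (2.63 ± 0.12) and spbC (2.15 ± 0.13). The cannibalism toxin list had a camera adjusted p of 1.09e-04, and an adjusted p of 0.321 with an estimated correlation. Secondary metabolite and bacteriocin genes counted 21 higher and 10 lower of 43, those of smallest p being the subtilosin maturation genes albD (3.70 ± 0.16) and albG (3.24 ± 0.16). For the secondary metabolite list, camera gave an adjusted p of 0.108, and an adjusted p of 0.401 with an estimated correlation. Without agar replicate 3 the camera adjusted p of this list was 0.0203. Motility and chemotaxis genes (SigD dependent) fell in 29 of 52 cases and rose in 6 (median -0.61), with the flagellin gene hag (-1.82 ± 0.17), motB (-1.29 ± 0.12) and the autolysin gene lytE (-1.94 ± 0.15) lower and the oxygen sensor gene hemAT (1.29 ± 0.13) higher. The motility and chemotaxis list had a camera adjusted p of 0.0123, and an adjusted p of 0.613 with an estimated correlation. Without agar replicate 1 this list had a camera adjusted p of 0.173, and with each array left out in turn 13 to 27 of its genes fell. Competence genes went both ways, with 6 higher and 8 lower of 28. For the competence list, camera gave an adjusted p of 0.664, and an adjusted p of 0.852 with an estimated correlation. None of the 4 tested poly-gamma-glutamate genes passed the test, capB lying below background and pgsA at -0.14 ± 0.13.

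Of the 10 largest fitted decreases, 5 lay in the manganese homeostasis, PerR and Zur lists. The 10 were rpsNB (-4.53 ± 0.19), oxdC (-4.44 ± 0.22), mrgA (-4.16 ± 0.22), yhbE (-4.02 ± 0.19), yhbF (-3.87 ± 0.21), katA (-3.77 ± 0.23), rodA (-3.71 ± 0.25, 2 arrays), mntA, mntH and folEB (at least 4.22-fold lower), all 10 with an adjusted p of at most 3.51e-06. The place of folEB, the only one of the Zur list, is not exact, since its bound is smaller than the measured decrease of znuA given below. Without agar replicates 1 and 2 in turn, rodA was at -3.12 and -4.31. The gene oxdC encodes oxalate decarboxylase, a manganese enzyme. All 14 genes of the PerR regulon (peroxide response) fell (median -1.79), including the mini-ferritin gene mrgA, the catalase gene katA, fur (-1.33 ± 0.12) and hemL (-1.71 ± 0.15). The PerR list had a camera adjusted p of 9.19e-06, and an adjusted p of 0.321 with an estimated correlation. All 8 tested genes of the Zur regulon, which is derepressed when zinc is short, fell as well (median -1.92), such as the zinc uptake gene znuA (-2.60 ± 0.14) and zinU (-1.87 ± 0.14). For the Zur list, camera gave an adjusted p of 0.00255, and an adjusted p of 0.321 with an estimated correlation. In the Fur regulon (iron uptake), 19 of 35 genes rose and 8 fell (median 0.56), with fbpB (2.71 ± 0.14) and the siderophore synthesis gene dhbA (2.32 ± 0.15) higher and ywjA (-1.46 ± 0.12) lower. The Fur list had a camera adjusted p of 0.027, and an adjusted p of 0.613 with an estimated correlation. Its camera adjusted p was 0.0519 without agar replicate 2 and 0.0576 without replicate 3. General stress genes (SigB dependent) fell in 31 of 38 cases and rose in 2 (median -0.99), for example akrN (-2.59 ± 0.15) and csbD (-2.21 ± 0.14). For the general stress list, camera gave an adjusted p of 9.19e-06, and an adjusted p of 0.387 with an estimated correlation. Oxidative stress enzymes counted 4 higher and 9 lower of 17, with trxB (-1.61 ± 0.12) lower and sodF (1.60 ± 0.13) higher. The oxidative stress list had a camera adjusted p of 0.257, and an adjusted p of 0.548 with an estimated correlation.

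In energy metabolism on agar, 26 of 33 genes of respiration and anaerobic growth rose and 1 fell (median 1.17), with the cytochrome maturation gene resA (2.74 ± 0.14), the anaerobic regulator gene fnr (2.73 ± 0.19) and the quinol oxidase gene qoxA (2.61 ± 0.17, 2 arrays). For the respiration list, camera gave an adjusted p of 2.73e-04, and an adjusted p of 0.536 with an estimated correlation. All 9 ATP synthase genes rose (median 1.23), for example atpF (1.69 ± 0.13). The ATP synthase list had a camera adjusted p of 5.60e-04, and an adjusted p of 0.401 with an estimated correlation. Ribosomal protein genes rose in 24 of 50 cases and fell in 2 (median 0.39), with rpsD (1.37 ± 0.16) and rpmA (-0.95 ± 0.12) as examples of each direction. For the ribosomal protein list, camera gave an adjusted p of 0.0139, and an adjusted p of 0.613 with an estimated correlation. Without agar replicate 3 that list had 14 higher genes, a median of 0.24 and a camera adjusted p of 0.0576. Arginine genes rose in 9 and fell in 5 of 18 cases (median 1.44), the 4 of smallest p being the synthesis genes argC (3.14 ± 0.12), argD (3.26 ± 0.12), argB (2.89 ± 0.12) and carB (3.40 ± 0.14). Under the alternatives the arginine median ranged from 0.20 to 3.15. The arginine list had a camera adjusted p of 0.0281, and an adjusted p of 0.549 with an estimated correlation. Synthesis of branched-chain amino acids fell in 9 of 11 genes (median -1.09), with ilvD (-2.12 ± 0.15), and pyrimidine synthesis in 9 of 10 (median -0.68), with pyrC (-0.81 ± 0.12). For the branched-chain amino acid list, camera gave an adjusted p of 0.00255, and an adjusted p of 0.536 with an estimated correlation. The pyrimidine list had a camera adjusted p of 0.0176, and an adjusted p of 0.385 with an estimated correlation. Sulfur amino acid genes counted 3 higher and 20 lower of 26 (median -1.17), including cysC (-2.37 ± 0.21) and mtnW (-1.69 ± 0.14). For the sulfur amino acid list, camera gave an adjusted p of 5.21e-04, and an adjusted p of 0.321 with an estimated correlation.

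The remaining lists did not stand apart from the other genes on agar. Of 19 genes of extracellular proteases and degradative enzymes, 3 were higher and 9 lower (camera adjusted p = 0.364). Of 17 genes of glycolysis, 3 were higher and 8 lower (camera adjusted p = 0.578). Of 13 genes of the TCA cycle, 1 was higher and 7 lower (camera adjusted p = 0.108). Of 19 genes of gluconeogenesis and overflow metabolism, 4 were higher and 9 lower (camera adjusted p = 0.337). Of 20 genes of purine synthesis, 5 were higher and 1 lower (camera adjusted p = 0.422). Of 15 genes of histidine and tryptophan synthesis, 0 were higher and 2 lower (camera adjusted p = 0.648). Of 16 genes of heat shock, 6 were higher and 7 lower (camera adjusted p = 0.648). Of 36 genes of cell wall stress, 20 were higher and 9 lower (camera adjusted p = 0.163). Of 29 genes of the PBSX prophage, 10 were higher and 1 lower (camera adjusted p = 0.143). Of 24 genes of phosphate starvation, 11 were higher and 8 lower (camera adjusted p = 0.914). The median of the histidine and tryptophan list differed in sign from its mean or test, and without agar replicate 1 it held 1 higher and 0 lower genes. Called members of these lists included ptsG (1.90 ± 0.15), vpr (-2.50 ± 0.18, 2 arrays), sdhA (-1.46 ± 0.15), lctE (1.60 ± 0.18), guaB (-1.26 ± 0.18), clpE (-1.30 ± 0.21), yeaA (1.38 ± 0.15), xkdU (1.76 ± 0.14) and tuaF (1.66 ± 0.19).

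In all, 2725 of 3999 genes changed on agar (1372 higher, 1353 lower), of which 758 rose and 586 fell at least 2-fold, 1344 together. Loess centres the ratios of every array near 0 (median log2 ratio -0.005 on agar and 0.001 in liquid). The balance of higher and lower genes therefore follows in part from the normalization, and a shift of all genes would not show. Of the 33 lists large enough for camera, 17 passed with the preset correlation of 0.01 and 0 with an estimated one, where 3 had an unadjusted p under 0.05 and the lowest adjusted p was 0.122. The rotation test fry, which asks whether a list's genes move one way on balance, called 27. The counts adjusted over the list alone equalled those over all genes tested for every list except early sporulation (0 higher, 6 lower), ribosomal proteins (22 and 2), glycolysis (4 and 8), histidine and tryptophan synthesis (0 and 1), general stress (3 and 31), cell wall stress (22 and 9), the PBSX prophage (7 and 1) and phosphate starvation (12 and 8). With each agar array left out in turn, further counts that changed more than 1.5 times were the higher genes of phosphate starvation (6 to 10), gluconeogenesis (2 to 3), manganese homeostasis (1 to 2) and general stress (1 to 2), and the lower ones of arginine (3 to 6), respiration (1 to 2), ribosomal proteins (1 to 2) and PBSX (0 to 1).

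In liquid, the check genes ran against the labels. The importer genes that MntR represses when manganese is plentiful were higher in the RNA labelled as with manganese, with mntA (3.23 ± 0.24), mntC (2.36 ± 0.23), mntB (1.95 ± 0.24), mntH (1.33 ± 0.21) and mntD (0.39 ± 0.10), on 4 of 4 arrays each and with an adjusted p of at most 0.00713. The exporter gene mneS was called lower (limma adjusted p = 0.0111) but lay below background in both conditions, as did mneP (limma adjusted p = 0.138), ykoY and yybP. The repressor gene mntR (at least 1.17-fold higher) was called, but not without liquid replicate 2 or 4 (limma adjusted p = 0.0518 and 0.0519), and mneS was not called without replicate 4 (limma adjusted p = 0.0846). The list of 10 held 6 higher and 1 lower genes. The manganese homeostasis list had a camera adjusted p of 0.133, and an adjusted p of 0.388 with an estimated correlation. The direction stated by the labels is kept for liquid below, as the RNA labelled as with manganese against that labelled as without it, and each direction in liquid turns if the labels of these 4 arrays are exchanged.

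**Figure D1:**
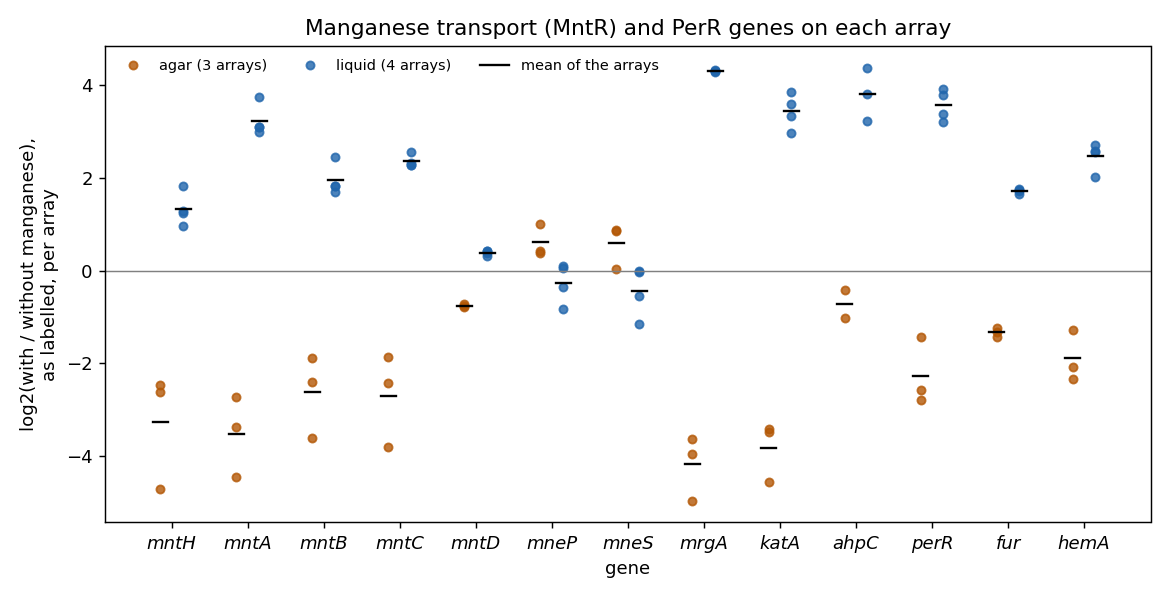
Log2 ratio of with over without manganese, as labelled, for genes of the MntR and PerR regulons (x axis) on each array, with 1 point per array for agar (orange) and liquid (blue) and a black bar for the mean of the arrays. The importer genes mntH and mntABCD and the PerR genes lie below 0 on the agar arrays and above 0 on the liquid arrays.

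As labelled, 6 of the 10 largest increases in liquid were in genes of the glycolysis and PerR lists. The 10 were gapA (5.38 ± 0.10), mrgA (4.31 ± 0.18), sufB (4.25 ± 0.19), alsD (3.96 ± 0.19), eno (3.87 ± 0.11), ahpC (3.76 ± 0.23, 3 arrays), sufU (3.61 ± 0.20), tpiA (3.59 ± 0.11), perR (3.58 ± 0.18) and sufC (3.54 ± 0.16), with an adjusted p of at most 3.94e-06. The gapA, tpiA and eno products catalyse steps of glycolysis, and the suf genes build iron-sulfur clusters. Glycolysis genes were higher in 14 and lower in 1 of 17 cases (median 0.73). For the glycolysis list, camera gave an adjusted p of 4.53e-05, and an adjusted p of 0.234 with an estimated correlation. All 14 PerR regulon genes were higher (median 1.96), including katA (3.44 ± 0.20) and fur (1.72 ± 0.10). The PerR list had a camera adjusted p of 3.02e-07, and an adjusted p of 0.274 with an estimated correlation. Of 17 oxidative stress enzymes, 11 were higher and 2 lower (median 1.16, or 0.74 with members at their bound), with the methionine sulfoxide reductase genes msrB (2.35 ± 0.10) and msrA (2.15 ± 0.10) and trxB (at least 7.04-fold higher). For the oxidative stress list, camera gave an adjusted p of 0.00175, and an adjusted p of 0.234 with an estimated correlation.

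The 10 largest fitted decreases in liquid are given as bounds, since the RNA labelled as with manganese was below background on every array. Their rank is therefore not exact, and measured decreases of genes outside these 10 can exceed some of the bounds. For example, the bounds of tasA and ybcS are smaller than the measured decrease of spoIIAB given further below. They were sboA (at least 68.5-fold lower), the subtilosin precursor gene, yjdB (at least 79-fold lower), yoqM (at least 48.6-fold lower), liaD (at least 67.8-fold lower), the acetoin dehydrogenase genes acoL (at least 51.5-fold lower) and acoA (at least 33.6-fold lower), the matrix fibre gene tasA (at least 20.8-fold lower), ybcS (at least 28.9-fold lower), skfE (at least 31.2-fold lower) and skfF (at least 32.8-fold lower), with an adjusted p of at most 1.05e-07. Of these, liaD had 3 arrays. Cannibalism toxin genes were lower in 10 and higher in 0 of 11 cases, with a median of -4.41, or -3.42 with members at their bound or at 0 where both conditions were below background. The cannibalism toxin list had a camera adjusted p of 1.53e-07, and an adjusted p of 0.234 with an estimated correlation. Secondary metabolite and bacteriocin genes counted 5 higher and 27 lower of 43 (median -0.58, 0.00 at the bounds), with albD (-3.79 ± 0.13) and albF (-3.88 ± 0.13). For the secondary metabolite list, camera gave an adjusted p of 2.20e-04, and an adjusted p of 0.234 with an estimated correlation. Biofilm matrix genes were lower in 17 of 19 cases and higher in 0 (median -1.71, -0.74 at the bounds), for example epsA (at least 5.05-fold lower) and bslA (at least 3.95-fold lower). The biofilm matrix list had a camera adjusted p of 2.20e-05, and an adjusted p of 0.388 with an estimated correlation.

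Early sporulation genes (Spo0A and SigH dependent) were lower in 10 and higher in 1 of 14 cases in liquid (median -2.65, -2.13 at the bounds). For the early sporulation list, camera gave an adjusted p of 2.24e-04, and an adjusted p of 0.388 with an estimated correlation. The operon that encodes SigF was among them, with spoIIAB (-4.94 ± 0.15), spoIIAA (-4.69 ± 0.13) and sigF (-4.65 ± 0.15), beside spoIIE (at least 11.1-fold lower). Later stages were mostly out of reach: 38 of 50 forespore, 37 of 43 early mother cell and 46 of 52 late mother cell genes lay below background in both conditions. Early mother cell genes counted 2 higher and 19 lower (median -0.31, 0.00 at the bounds), and without liquid replicate 4 there were 11 lower ones, with a median of -0.19 and a camera adjusted p of 0.0563. The early mother cell list had a camera adjusted p of 0.0144, and an adjusted p of 0.693 with an estimated correlation. With only probes above background in at least 1 channel on every liquid array, 1 of them was left, uncalled and at 0.26. Forespore genes counted 5 higher and 10 lower, sspH (at least 5.78-fold lower) and sigG (at least 2.58-fold lower) among the latter. For the forespore list, camera gave an adjusted p of 0.647, and an adjusted p of 0.821 with an estimated correlation. Late mother cell genes counted 2 higher and 6 lower, with gerE (-0.92 ± 0.16). The late mother cell list had a camera adjusted p of 0.492, and an adjusted p of 0.843 with an estimated correlation. Biofilm and sporulation regulators went both ways, 8 higher and 6 lower of 23, the phosphorelay gene spo0F (-2.28 ± 0.13) lower and kinD (at least 3.76-fold higher) higher. For the biofilm and sporulation regulator list, camera gave an adjusted p of 0.785, and an adjusted p of 0.891 with an estimated correlation.

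Motility and chemotaxis genes were higher in 49 and lower in 0 of 52 cases in liquid, as labelled (median 1.60, 0.99 at the bounds), with hag (3.42 ± 0.14), motB (2.93 ± 0.10) and flgE (at least 8.4-fold higher). The motility and chemotaxis list had a camera adjusted p of 1.50e-14, and an adjusted p of 0.388 with an estimated correlation. Competence genes (ComK dependent) counted 21 higher and 4 lower of 28 (median 1.24, 0.30 at the bounds), with the single-strand binding protein gene ssbB (2.41 ± 0.13) higher and bdbD (-1.55 ± 0.12) lower. For the competence list, camera gave an adjusted p of 0.00201, and an adjusted p of 0.388 with an estimated correlation. Respiration and anaerobic growth genes were lower in 29 and higher in 0 of 33 cases (median -1.95, -1.40 at the bounds), with the cytochrome c oxidase genes ctaF (-4.29 ± 0.13) and ctaD (-4.07 ± 0.13). The respiration list had a camera adjusted p of 7.24e-09, and an adjusted p of 0.388 with an estimated correlation. All 9 ATP synthase genes were lower (median -3.15), such as atpH (-3.31 ± 0.10). For the ATP synthase list, camera gave an adjusted p of 1.53e-07, and an adjusted p of 0.274 with an estimated correlation. Ribosomal protein genes counted 7 higher and 35 lower of 50 (median -0.89, -0.83 at the bounds), with rpsC (-2.45 ± 0.12). The ribosomal protein list had a camera adjusted p of 5.09e-07, and an adjusted p of 0.388 with an estimated correlation. Arginine genes counted 1 higher and 11 lower of 18 (median -0.43, 0.00 at the bounds), and those of smallest p were the degradation genes rocA (at least 20.6-fold lower) and rocD (-3.74 ± 0.11). For the arginine list, camera gave an adjusted p of 0.0148, and an adjusted p of 0.458 with an estimated correlation. Branched-chain amino acid genes were higher in 8 of 11 cases (median 0.79, 0.08 at the bounds), for example ilvC (at least 2.83-fold higher). The branched-chain amino acid list had a camera adjusted p of 0.00175, and an adjusted p of 0.442 with an estimated correlation. Cell wall stress genes were lower in 22 and higher in 6 of 36 cases (median -0.55, -0.01 at the bounds), with the sigma factor gene sigW (-2.56 ± 0.12). For the cell wall stress list, camera gave an adjusted p of 0.00807, and an adjusted p of 0.423 with an estimated correlation. PBSX prophage genes counted 1 higher and 14 lower of 29, 25 of them below background in both conditions (median -0.36, 0.00 at the bounds), with xkdF (-1.89 ± 0.15). The PBSX list had a camera adjusted p of 0.00438, and an adjusted p of 0.442 with an estimated correlation.

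A further 12 lists did not stand apart in liquid. Of 35 genes of the Fur regulon, 15 were higher and 8 lower (camera adjusted p = 0.179). Of 8 genes of the Zur regulon, 2 were higher and 0 lower (camera adjusted p = 0.557). Of 38 genes of general stress, 6 were higher and 10 lower (camera adjusted p = 0.647). Of 19 genes of extracellular proteases and degradative enzymes, 1 was higher and 8 lower (camera adjusted p = 0.0501). Of 13 genes of the TCA cycle, 5 were higher and 2 lower (camera adjusted p = 0.647). Of 19 genes of gluconeogenesis and overflow metabolism, 6 were higher and 9 lower (camera adjusted p = 0.313). Of 20 genes of purine synthesis, 3 were higher and 0 lower (camera adjusted p = 0.647). Of 10 genes of pyrimidine synthesis, 1 was higher and 0 lower (camera adjusted p = 0.647). Of 15 genes of histidine and tryptophan synthesis, 2 were higher and 2 lower (camera adjusted p = 0.94). Of 26 genes of sulfur amino acid metabolism, 11 were higher and 7 lower (camera adjusted p = 0.759). Of 16 genes of heat shock, 6 were higher and 2 lower (camera adjusted p = 0.647). Of 24 genes of phosphate starvation, 4 were higher and 5 lower (camera adjusted p = 0.785). Median, mean and test differed in sign for the forespore, TCA cycle and purine lists. The proteases had a camera adjusted p of 0.0353 without liquid replicate 1 and 0.037 without replicate 2, both with the preset correlation only. In the Zur list, 7 of the 8 genes were below background in both conditions, and without liquid replicate 4 none was called. The call in the pyrimidine list, pyrR, was lost without liquid replicate 1 (limma adjusted p = 0.173) or 2 (limma adjusted p = 0.0985), and the purine list held 2 higher genes without replicate 1, 3 or 4. Named members were the iron uptake genes efeM (1.96 ± 0.11) and feuA (1.44 ± 0.15), the stress genes dps (-2.13 ± 0.12) and gabD (1.52 ± 0.11), xynA (-3.20 ± 0.11), citZ (-2.26 ± 0.13), citB (0.93 ± 0.11), alsS (3.15 ± 0.13), guaB (2.39 ± 0.15), mtnA (1.21 ± 0.13), sat (-1.48 ± 0.16), clpP (1.21 ± 0.12), groES (-1.34 ± 0.17) and tagD (3.11 ± 0.15). Of 4 poly-gamma-glutamate genes, 2 were called higher and 1 lower, with pgdS (at least 3.32-fold higher). The lower one, capB, lay below background in both conditions, and without liquid replicate 1, 2 or 4 only 1 higher gene was left.

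In all, 2144 of 3999 genes were called in liquid, 1055 higher and 1089 lower in the RNA labelled as with manganese, of which 351 and 540 by at least 2-fold, 891 together. Restricting the test to the 1290 probes above background in at least 1 channel on every liquid array left 1088 called genes. Of 33 lists, 17 passed camera with the preset correlation and 0 with an estimated one, where 6 had an unadjusted p under 0.05 and the lowest adjusted p was 0.234. Fry called 23. Counts adjusted over the list alone differed from those over all genes tested for forespore (3 higher, 8 lower), late mother cell (2 and 5), oxidative stress (11 and 3), general stress (6 and 9), secondary metabolites (7 and 27), purine synthesis (2 and 0), pyrimidine synthesis (0 and 0), branched-chain amino acids (9 and 0), sulfur amino acids (12 and 7) and cell wall stress (6 and 24). With each liquid array left out in turn, the higher genes were 3 to 4 for forespore, 2 to 6 for general stress, 3 to 5 for heat shock, 3 to 5 for the TCA cycle and 2 to 5 for secondary metabolites, and 0 to 1 for early sporulation, 1 to 2 for early mother cell, 1 to 2 for late mother cell and 0 for PBSX. The lower ones were 11 to 22 for early mother cell, 7 to 15 for forespore, 6 to 16 for PBSX, 7 to 12 for arginine, 5 to 7 for Fur, 3 to 5 for phosphate starvation, 1 to 3 for oxidative stress and 0 to 1 for manganese homeostasis. Counts of the other lists, apart from those given above, stayed within 1.5 times.

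The manganese effect differed between the experiments, as labelled, for 2912 of 3999 genes (agar minus liquid contrast of the joint fit), with 1572 differences positive and 1340 negative. In liquid, 1905 of the 3999 genes were below background in both conditions on every array, so their differences rest mainly on the agar values. Of the 1242 genes above background in at least 1 channel on every array with a value, 1048 were called. Among the positive fitted differences of most size were sboA (10.37 ± 0.48), sboX (9.88 ± 0.47), yoqM (9.69 ± 0.51), yjdB (9.38 ± 0.29) and ybcS (8.46 ± 0.17), and except for sboX they rest on liquid values with a condition below background on every array. Among the negative ones were mrgA (-8.46 ± 0.28), katA (-7.21 ± 0.31), yhbF (-6.98 ± 0.27), yhbE (-6.91 ± 0.25) and mntA (-6.71 ± 0.37), where yhbF and yhbE had a condition below background in liquid, so the differences of these 6 genes are not exact and no order is given. Leaving out agar replicate 1 gave sboA 11.47, sboX 11.09, yoqM 10.66, yjdB 9.999 and mntA -7.33, and sboX was 8.67 without agar replicate 2. Every one of these 10 had an adjusted p of at most 2.02e-07. Across genes, the mean effects on agar and in liquid correlated with Pearson's r = -0.32 and Spearman's rho = -0.41, and r was -0.53 over the 1242 genes above background in at least 1 channel on every array with a value. As many as 545 genes were higher on agar and lower in liquid, against 374 if the calls were independent, and 638 were lower on agar and higher in liquid against 357. In both experiments 126 genes were higher (362 if independent) and 222 lower (368 if independent).

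Among the lists, 23 of 33 differed between the experiments by camera with the preset correlation and 0 with an estimated one, where 5 had an unadjusted p under 0.05 and the lowest adjusted p was 0.277. Fry called 28. The difference was positive for 13 of the 23, among which were cannibalism toxins (median 6.57), late mother cell genes (median 4.07) and biofilm matrix genes (median 3.84). For the cannibalism toxin list, camera gave an adjusted p of 5.67e-06, and an adjusted p of 0.279 with an estimated correlation. The late mother cell list had a camera adjusted p of 4.45e-11, and an adjusted p of 0.279 with an estimated correlation. For the biofilm matrix list, camera gave an adjusted p of 2.32e-05, and an adjusted p of 0.329 with an estimated correlation. It was negative for 10, including the PerR regulon (median -4.00), motility and chemotaxis (median -1.92) and the Zur regulon (median -1.83). The PerR list had a camera adjusted p of 7.18e-07, and an adjusted p of 0.279 with an estimated correlation. For the motility and chemotaxis list, camera gave an adjusted p of 3.45e-09, and an adjusted p of 0.329 with an estimated correlation. The Zur list had a camera adjusted p of 0.00578, and an adjusted p of 0.31 with an estimated correlation. In liquid, most genes of the late mother cell and Zur lists lay below background in both conditions, so the differences of these lists rest mainly on the agar values. Adjusted over the list alone, counts of differing genes were not those over all genes tested for the regulators (10 higher, 11 lower), PBSX (12 and 0) and histidine and tryptophan (1 and 1). Median, mean and test differed in sign for the protease, purine and phosphate starvation lists. The 10 lists that passed camera with the preset correlation in both experiments had opposite directions in all 10 cases. None of them passed with an estimated correlation, and by construction all 10 would have the same direction with the liquid labels exchanged. Opposite list directions do not show that the same genes turned. For arginine, the genes of smallest p were synthesis genes on agar and degradation genes in liquid. Most early mother cell genes lay below background in both conditions in liquid. With the labels of the liquid arrays exchanged, 2276 genes differed, with 1156 differences positive and 1120 negative. By construction, r became 0.32 and rho 0.41, and the joint counts became 545 genes higher and 638 lower in both experiments. The differences then were 0.15 for mrgA, -0.34 for katA and -0.25 for mntA, all uncalled. Camera then called 16 lists with the preset correlation, 8 positive and 8 negative, and 0 with an estimated one. The list medians then were -2.40 for cannibalism toxins, 3.88 for late mother cell genes, 0.63 for biofilm matrix genes, 0.06 for the PerR regulon, 1.04 for motility and -2.01 for the Zur regulon. Growth format, culture time and slide series all differ between the experiments and cannot be told apart.

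**Figure D2:**
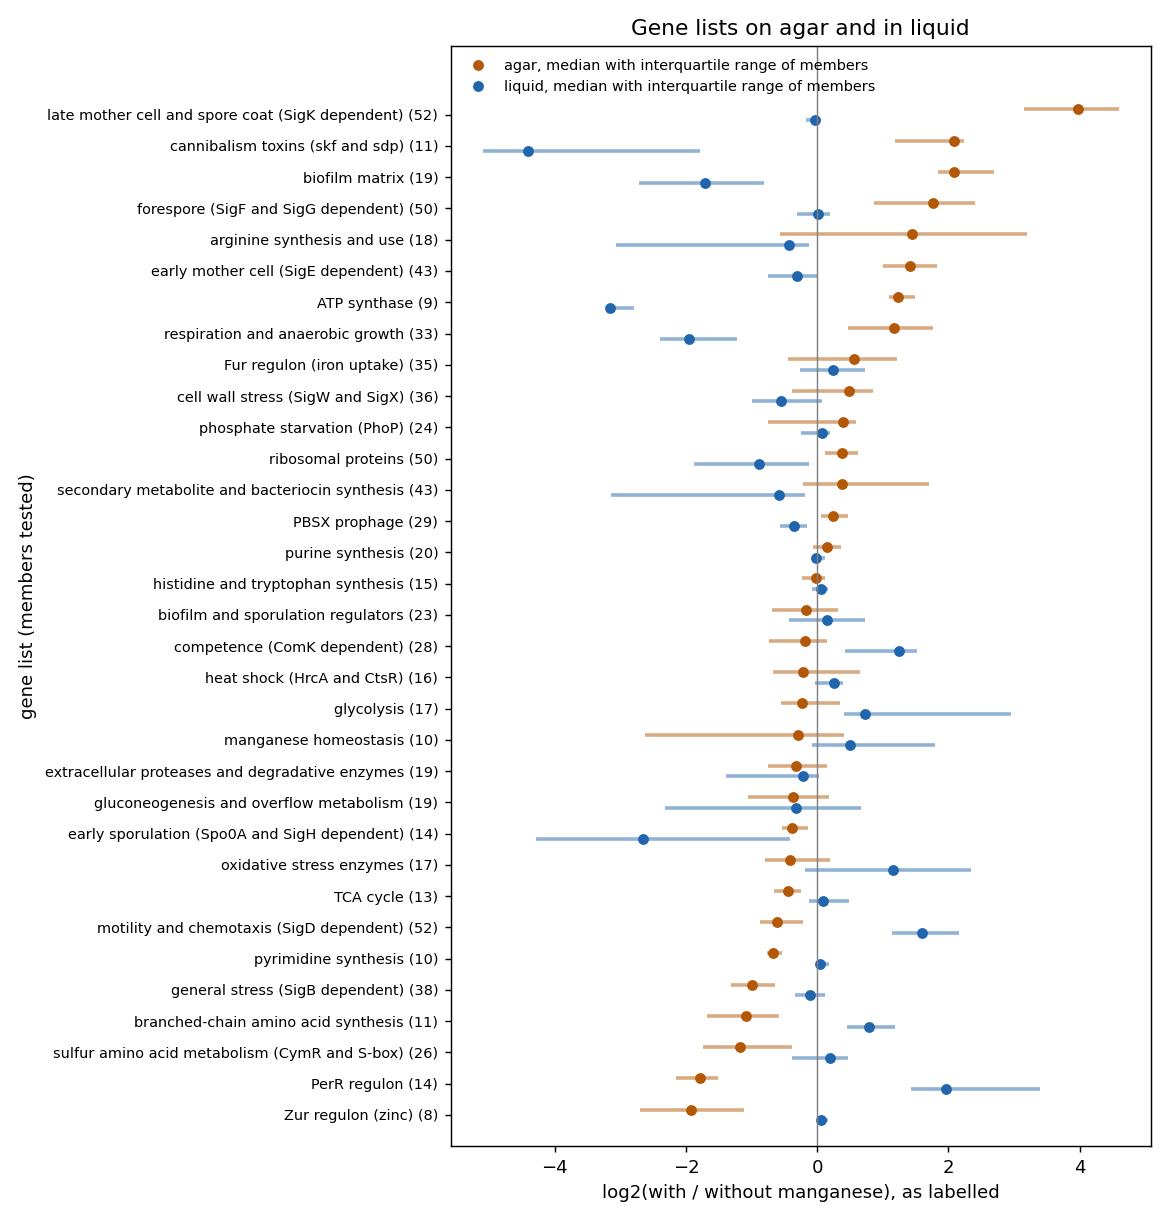
Median log2 ratio of with over without manganese, as labelled (x axis), of the tested members of each gene list (y axis, number of members in parentheses), with a line for the interquartile range, on agar (orange) and in liquid (blue). The late mother cell list lies highest on agar, at 3.97, and near 0 in liquid, at -0.03. In liquid, 46 of its 52 genes were below background in both conditions on every array, so that median does not show an absence of change.

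**Figure D3:**
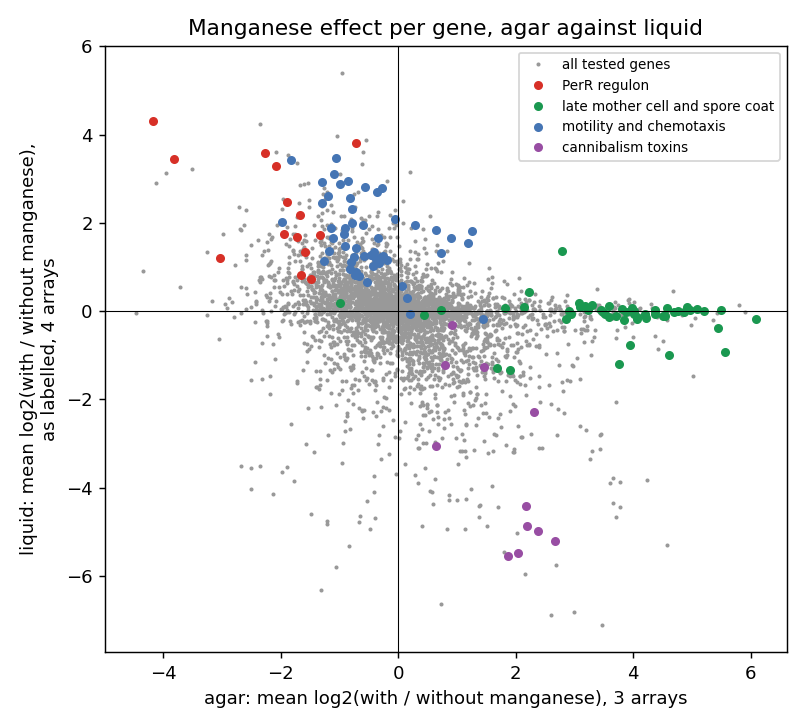
Mean log2 ratio of with over without manganese on the 3 agar arrays (x axis) against that on the 4 liquid arrays, as labelled (y axis), with 1 point per tested gene and 4 lists in colour. PerR regulon genes lie to the upper left and cannibalism toxin genes to the lower right, and over the 3999 genes Pearson's r is -0.32.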

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

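All tests of explanations below, the splits of the arrays included, were chosen after the results were seen, as were the control probes, while the test of the difference between the experiments was planned.

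In liquid, 1905 of 3999 genes were below background in both conditions on every array, so any difference of theirs rests mainly on the agar values. The effect of manganese differed between agar and liquid, as labelled, for 2912 genes in limma's test of the difference itself. In 35 splits of the 7 arrays into 3 and 4, 1 split, the real one, gave as many, and the highest other gave 12. Growth format, culture time and slide series follow the real split, and this test was chosen after the results were seen. It therefore shows that the arrays group by experiment and does not exclude chance for this count. For the single experiments the orientations of the arrays allow too few splits, 4 on agar (real 2725, highest other 65) and 8 in liquid (real 2144, highest other 0 by limma, with 294 genes at an unadjusted p under 0.05), where in each 1 split, the real one, gave as many. Fitted differences in log2 ratio included sboA 10.37, yoqM 9.69, yjdB 9.38, ybcS 8.46, yhbF -6.98 and yhbE -6.91, which are not exact because 1 condition was below background on every liquid array, and sboX 9.88, mrgA -8.46, katA -7.21 and mntA -6.71. With the liquid labels exchanged the last 4 were -0.72, 0.15, -0.34 and -0.25, all uncalled.

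Lists differed by camera with the preset correlation, and none of these calls held with an estimated one (0 of 33, with 5 at an unadjusted p under 0.05, and 28 called by fry). The median differences are followed by those with values set to their bounds (0 where both conditions were below background) and those with the liquid labels exchanged. Positive medians were found for arginine (3.24, 3.14, 1.24), ATP synthase (4.42, 4.28, -1.65), biofilm matrix (3.84, 3.00, 0.63), cannibalism toxins (6.57, 5.58, -2.40), cell wall stress (1.35, 0.93, -0.16), early mother cell (1.98, 1.42, 0.94), early sporulation (2.45, 1.88, -2.77), forespore (1.98, 1.99, 1.47), late mother cell (4.07, 4.00, 3.88), PBSX (0.53, 0.24, -0.20), respiration (3.23, 3.02, -0.29), ribosomal proteins (1.52, 1.38, -0.59) and secondary metabolites (1.08, 0.86, -0.37). Negative ones were found for branched-chain amino acids (-1.85, -1.61, -0.26), competence (-1.49, -0.61, 0.85), general stress (-0.81, -0.91, -1.26), glycolysis (-1.01, -1.01, 1.39), motility (-1.92, -1.25, 1.04), oxidative stress (-1.21, -1.05, 1.19), PerR (-4.00, -3.71, 0.06), pyrimidines (-0.71, -0.68, -0.62), sulfur amino acids (-1.11, -1.11, -0.73) and Zur (-1.83, -1.87, -2.01). With the labels exchanged camera called 16 lists with the preset correlation and 0 with an estimated one, and the labels were not shown to be wrong. The camera call of competence was lost without agar replicate 1 (adjusted p = 0.0525), and that of cell wall stress without agar replicate 1 (adjusted p = 0.0621) or liquid replicate 2 (adjusted p = 0.059). The early mother cell median was -0.17 where 1 gene was left above background in at least 1 channel on every array.

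Genes of the MntR and PerR regulons moved in opposite directions on agar and in liquid, in 20 of the 20 genes called in both experiments. A wrong orientation of 1 to 3 liquid arrays is argued against by the lowest correlation between oriented liquid arrays, 0.906, and a dye effect by the medians of these genes on liquid arrays with the manganese label in Cy5 (1.74) and in Cy3 (1.82). An exchange of with and without manganese in the labels of all 4 liquid arrays would turn these genes by construction, so the count of 20 neither supports nor excludes it. It cannot be told apart from a biological effect of growth format or culture time, with 0 further experiments in either format.

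Blocks on agar replicate 3 and liquid replicate 4 were out of line with the other arrays. Spots read 1 column off may account for agar replicate 3, where 12 of the 12 blocks that could be measured lined up once moved. On liquid replicate 4, 1 of 7 did, block 36, at a rho of 0.947. The blocks of liquid replicate 4 had a median signal of -0.00974 times that of its other blocks. With so little signal, a failure to line up cannot argue against a shift there. Weak hybridisation may account for the low signal but was not told apart from spots read off. For agar replicate 3 the ratio of 0.618 leaves weak hybridisation open. No biological explanation was tested.

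Late mother cell genes rose on agar and few were called in liquid, where 46 of 52 were below background in both conditions. Too little signal in liquid for a change to show may account for this. Growth format or culture time cannot be told apart from it, with 0 further experiments in either format.

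By its gap over the range of the 4 arrays, a single liquid array was flagged for 5 of 142 named genes, against 7.1 that chance gives at 1 in 20. The measure is relative, so a flagged array can lie close to the others, as for sufC at 3.49 against 3.56 to 3.57. As the gap over the range, the values were 0.845 for mntA (replicate 1), 0.847 for sufC (replicate 2), 0.889 for albF (replicate 1), 0.901 for ctaD (replicate 3) and 0.842 for cysH (replicate 1). Control probes, which are in no comparison, were above background in every spot and channel for 7 of 15 probes on the agar arrays, 4 named for luciferase and 3 for ribosomal RNA, and for 3 of 42 on the liquid arrays.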

How the results depend on the processing

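The alternatives were planned except the left-out blocks kept or moved and the liquid labels exchanged, which were chosen after seeing the data. Counts of called genes stayed within 1.5 times under each alternative run, except for liquid 1088 and the difference 1048 with only probes above background in at least 1 channel on every array, where fewer genes were tested, and agar 1344 and liquid 891 with at least 2-fold required, a stricter threshold. Without each array in turn they were 2178 to 2501 (agar), 1726 to 2115 (liquid) and 2579 to 2874 (difference). With the left-out blocks kept they were 2285, 1550 and 2503, and with them moved 2538, 1849 and 2730. The correlation between experiments was -0.53 with this filter, where the cause was not tested, and by construction 0.32 with the liquid labels exchanged. Of the gene lists, 0 on agar, 0 in liquid and 0 for the difference passed camera with an estimated correlation, and 27 passed fry on agar, which asks another question. For named genes, 5708 values kept direction and side of the threshold, 169 lost the threshold, 8 gained it and 19 turned. Those that turned were yybP in liquid (0.00148 without background correction, 0.10 with print-tip loess, 0.017 with blocks moved), ftsA on agar (0.12 with print-tip loess), and on agar mntR (-0.29), ykoY (-0.24) and capB (0.92) with median centring, and capB with the deposited values (0.14); the cause was not tested. Leaving out each array in turn gave mntR -0.25 to 0.78 and ykoY -0.072 to 0.24 on agar, and ykoY -0.17 to 0.016 and yybP -0.087 to 0.14 in liquid. With the liquid labels exchanged the differences that turned were sboA -3.85, sboX -0.72, yoqM -3.95, yjdB -4.41, ybcS -3.06 and mrgA 0.15. Of those that kept their sign, katA -0.34 (limma adjusted p = 0.366) and mntA -0.25 (0.583) lost the threshold, and yhbF -0.75 (0.0375) and yhbE -1.12 (0.00353) kept it. The exchange turns each liquid effect, and whether a difference turns depends on the sizes of the agar and liquid effects. The lists called before or after the exchange whose camera direction turned were, with their medians, early sporulation -2.77, competence 0.85, motility 1.04, PerR 0.062, oxidative stress 1.19, cannibalism toxins -2.40, secondary metabolites -0.37, proteases -0.66, glycolysis 1.39, respiration -0.29, ATP synthase -1.65, ribosomal proteins -0.59, cell wall stress -0.16 and PBSX -0.20, and camera called 16 lists. The protease median was already negative before the exchange (-0.096). The median of the biofilm and sporulation regulators turned from -0.36 to 0.14, and that list was called in neither case. Of the operon medians, 159 stayed, 35 moved beyond their spread and 0 turned. Quantile normalization of average intensity leaves the log ratios unchanged and gave no separate values. Signal over background limits liquid, where 1905 of 3999 genes were below background in both conditions.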

Other observations

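The operons below are outside the gene lists and were chosen after their values were seen, as were both tests.

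Some operons moved together in both experiments. The 10 genes of inositol catabolism were called lower on agar (median -2.15) and in the liquid RNA labelled as with manganese (median -3.54, 9 of 10 with a condition below background). With print-tip loess these medians were -0.34 and -1.84, and without liquid replicate 3 the liquid one was -4.20. Thiamine synthesis genes were lower in 6 of 7 cases on agar (median -1.18) and 7 of 7 in liquid (-1.71), and biotin synthesis genes in 4 of 6 (-0.64) and 6 of 6 (-1.45). Ribose uptake genes counted 3 higher and 1 lower of 6 on agar (median 0.21) and 6 lower in liquid (-3.71, 3 with a condition below background). The 5 genes of iron-sulfur cluster assembly were lower on agar (median -1.98) and higher in liquid (3.54).

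The hypothesis that inositol catabolism genes moved the same way in both experiments as labelled was met by 10 of 10 genes, and the hypothesis that iron-sulfur cluster assembly genes moved like the PerR regulon on 7 of 7 arrays. Neither decides anything, because the operons were picked for these values.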
